A study of Drosophila melanogaster with 17 samples.

How the data were processed

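Messenger RNA was measured by sequencing in escargot-positive (esg+) cells of the adult Drosophila midgut, the stem cells and enteroblasts in which the esg-Gal4 driver is active. Per the labels, flies carried esg-Gal4, UAS-GFP and a temperature-sensitive Gal80, were kept at 18 °C until adulthood and were moved to 29 °C for 2 days, which switches the UAS transgenes on. GFP-positive cells were sorted by flow cytometry from pools of about 100 midguts, with 20000 to 40000 cells per library. Each replicate was a separate pool of guts. RNA was isolated with a PicoPure kit, amplified with a RiboAmp kit and made into stranded mRNA libraries. The genotypes were run in 2 batches with their own controls. Batch 1 held 3 controls, 2 libraries with monomeric daughterless (da) overexpressed and 3 libraries with da knocked down by RNAi, read as single reads of 50 nt. Batch 2 held 3 controls, 3 libraries with the tethered homodimer da:da and 3 libraries with scute (sc) overexpressed, read as paired reads of 150 nt.

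The deposited counts per library are raw read counts per gene, which the authors made with featureCounts version 2.0.2 on exons of the BDGP6.28 genome, annotation release 101, per the file headers. No strand option was given for any of the 17 libraries. Multi-mapping reads and reads that overlap several genes were not counted. The headers show that the 9 libraries of batch 2 were given as paired-end input but counted without the option that counts read pairs, so each mate added 1 count. Of the counts between 1 and 30, 52.5% to 58.5% were even in batch 2, against 41.4% to 44.2% in batch 1. The aligner is named only by a folder in the headers. The deposited summary counts gave the share of reads assigned to genes as 88.7% to 90.6% in batch 1 and 80.2% to 84.1% in batch 2. Reads not assigned were multi-mapping (3.86% to 5.14% in batch 1, 6.22% to 7.72% in batch 2), outside annotated exons (1.22% to 2.22%, and 4.41% to 7.34%) or ambiguous (4.04% to 4.52%, and 4.86% to 5.49%). The authors also deposited a workbook with log2 fold changes and adjusted p-values of 4 comparisons, made with DESeq2 per its title sheet, which states neither design nor version. These log2 values and each adjusted p-value are described only as the authors' values. The workbook's sheet of counts, with 17 columns, was not used, because it gives no gene identifiers and numbers the da knock-down and da overexpression replicates differently from the labels.

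Every count file listed 17807 genes by FlyBase identifier. Symbols came from the authors' sheets for 9986 genes and from a later annotation of the same genome for 7762, and 59 genes had no symbol. Because counting ignored strand, exon overlap was checked: 64 of 249 named genes shared exon bases with another gene, and 3 of them (Mcm7, Hsp67Ba and dpn) shared over 50% with an antisense gene.

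Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr by group, libraries were scaled with TMM, and 1 mean per group was fitted to all libraries of a batch with the edgeR quasi-likelihood method. In batch 1, 9540 genes were tested and in batch 2 14190. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p of single genes below come from this test. Differences between changes of different batches were tested in 1 fit of all 17 libraries with 14083 genes, as the change against the control of one batch minus that of the other, which removes what a batch does alike to all its libraries. The biological coefficient of variation was 0.219 in batch 1, 0.203 in batch 2 and 0.212 over all libraries. Levels are CPM values of edgeR, which are counts divided by the TMM-scaled library size, as mean ± SD, and log2 fold changes carry their standard error (SE), taken from the fold change and its F statistic.

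There were 25 gene lists: progenitor, Notch response, proneural commitment, enteroendocrine regulators and secretion, gut peptide hormones, enterocyte regulators and structure, digestive enzymes, DNA replication, mitosis, bHLH partners, EGFR and JAK-STAT targets, antimicrobial peptides, heat shock, ribosomal proteins, oxidative phosphorylation, mitochondrial genome, V-ATPase, visceral muscle, haemocyte, neuron and glia, trachea, fat body, germline, Malpighian tubule and transgene markers. The overexpressed or targeted gene was left out of its own lists. Lists were tested with camera, two-sided, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, both adjusted over all lists of a comparison. Fry was run beside them. Calls of members were counted over all genes tested and adjusted over the list alone.

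Named genes followed a rule. It names da, sc and emc, 9 marker genes (esg, Dl, Su(H), pros, nub, klu, phyl, ase and tap), and, in the comparisons with controls and between scute and da:da, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between groups, which chance gives in 10% of genes for 3 libraries against 3. It also names up to 4 called members of a list with the lowest p, or 1 member where none was called, and the 5 genes with the lowest p each way for the differences of changes. Samples, comparisons, lists, this rule and the first set of alternatives were fixed before the data were examined.

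Whether replicate numbers pair libraries was checked from the correlation of residuals across genes. Knock-down and control libraries with the same number gave 0.187, 0.190 and 0.287, and those with unlike numbers -0.251 to 0.0154. The numbers were therefore read as pairs. With 3 libraries per group few matchings are possible, so this reading is tentative. This pairing and every blocked total rest on the labels' numbers being right, and the workbook's sheet numbers the replicates of both da groups otherwise. Libraries of da overexpression with the same number as a control gave -0.09 and -0.23, and batch 2 showed no pairing. With the numbers 1 and 2 crossed, da overexpression and control libraries gave 0.0903 and 0.233. The residuals of 2 libraries in a group are opposite, so these positive values follow by construction and add no evidence. The main comparisons hold no block, so p-values of single genes and lists in the knock-down ignore the pairing unless a block is named. Blocked values are given for the knock-down as totals and where a call moved.

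Alternatives were DESeq2 size factors in edgeR, no filter (any gene with at least 1 count), a stricter filter of 5 CPM, the DESeq2 Wald test, a fit of the compared groups only, a fit of all libraries, a replicate block, each library left out in turn, and a required absolute log2 fold change of 1. Added after the data were seen were halved batch 2 counts, a block with knock-down and control libraries only, and a block with the 2 da overexpression numbers crossed. Agreement between comparisons was measured across the genes tested in both. For pairs that share controls, 20 simulated sets of unchanged groups gave the level that shared controls alone produce, since 3 controls cannot be divided. Other splits of the same libraries were counted where both groups held 3.

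The comparisons were tested on simulated data with known changes. At a simulated change of 2-fold, the da and the knock-down comparison each recovered 59.7%, da:da recovered 53.7% and scute 50.7%. The differences of changes recovered 19.4% (da:da) and 25.4% (scute) at 2-fold, and 71.2% and 72.7% at 4-fold. False calls numbered 1 to 8 per comparison. At each simulated size 65 to 67 genes were changed, beside the mitosis list, far fewer than were called in the real comparisons. The recovered shares need not hold for those. Where a group held 0 counts of a gene, the fold was given against a floor of 3 counts over the group. Intervals of count ratios are exact at 95%, and intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.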

Results

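The transcriptomes of sorted esg+ progenitor cells were compared between genotypes that raise or lower bHLH transcription factors. Daughterless (Da) is the fly E protein, which binds DNA as a homodimer or as a heterodimer with proneural proteins such as Scute (Sc), and Extramacrochaetae (Emc) is an inhibitor that lacks a DNA-binding region. Batch 1 held 3 control libraries, 2 with monomeric da overexpressed and 3 with da knocked down. Batch 2 held 3 control libraries, 3 with the tethered homodimer da:da and 3 with scute overexpressed. Each replicate was a separate pool of about 100 guts. Reads assigned to genes numbered 33889877 to 40868714 per library in batch 1 and 47136298 to 66679229 in batch 2, where each mate of a pair was counted. Genes with at least 1 count numbered 11483 to 12432 per library in batch 1 and 15796 to 16238 in batch 2. Levels are given in CPM, counts scaled to library size. The mitochondrial large ribosomal RNA took the most counts in every library, 5.68% to 7.46% of counts in batch 1 and 11.5% to 17.2% in batch 2.

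The RNA counts of the manipulated genes showed the direction of each manipulation. The gene da (FBgn0267821) lies on chromosome 2L at 10388105 to 10393228 of BDGP6.28, sc on X at 396060 to 397497 and emc on 3L at 749400 to 753492. With monomeric da overexpressed, da was at 871 ± 36.5 CPM (SD, n = 2) against 112 ± 22.5 in controls (n = 3), a 7.74-fold rise (adjusted p = 2e-05). The knock-down left da at 27.9 ± 6.97 CPM (n = 3), 4.03-fold lower (adjusted p = 0.000285). In batch 2, da:da libraries held da at 218 ± 24.3 CPM against 77.5 ± 1.99 (n = 3 each), 2.82-fold higher (adjusted p = 1.27e-06). Scute overexpression brought sc from 1.77 ± 0.0583 to 2062 ± 506 CPM (n = 3 each), 1164-fold higher (adjusted p = 5.68e-10), while da did not pass (log2 change 0.17 ± 0.10 SE, adjusted p = 0.187, and 0.0303 with the stricter filter). Counts of da and sc include reads of the transgenes, so these folds do not compare the doses of different constructs.

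The inhibitor gene emc and the endogenous sc gene followed the da manipulations in opposite directions. Emc rose from 36.5 ± 2.43 to 763 ± 70.9 CPM with da (20.9-fold, adjusted p = 6.55e-07) and from 49.8 ± 11.4 to 1689 ± 19.99 CPM with da:da (33.9-fold, adjusted p = 4.84e-08). It fell to 12.4 ± 2.19 CPM in the knock-down (log2 change -1.56 ± 0.15, adjusted p = 0.00023) and rose modestly with scute, to 85.7 ± 14.1 CPM (log2 change 0.78 ± 0.16, adjusted p = 0.00179). The sc gene fell with da (log2 change -2.17 ± 0.32, adjusted p = 0.00118) and with da:da (-2.00 ± 0.25, adjusted p = 0.00026), and rose in the knock-down (1.35 ± 0.24, adjusted p = 0.00481). The rise of emc did not differ detectably between da:da and da (difference of log2 changes 0.77, adjusted p = 0.057), and that with scute was smaller than that with da (-3.56, adjusted p = 7.36e-09).

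**Figure D1:**
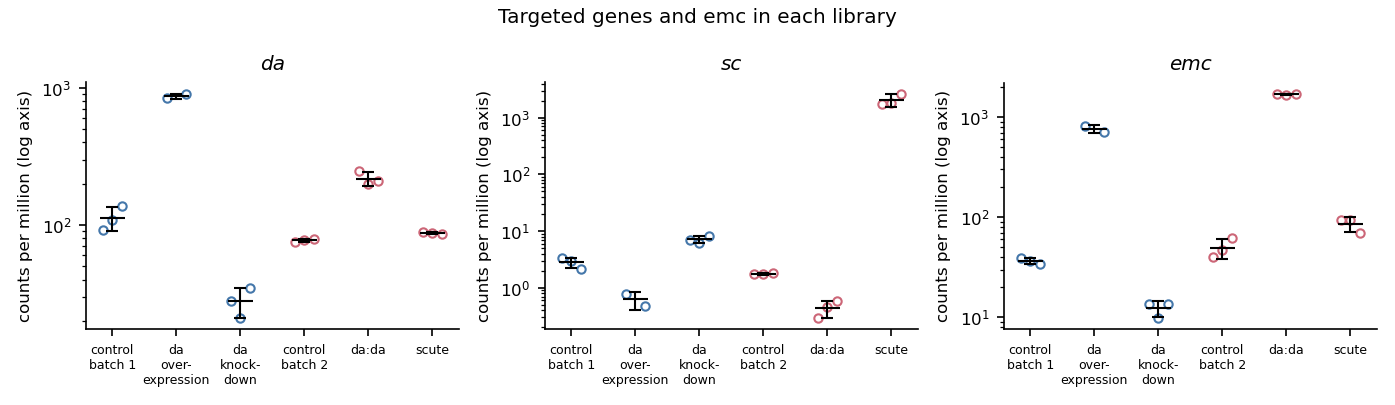
CPM of da, sc and emc in each of the 17 libraries on a log axis, by group, with batch 1 in blue and batch 2 in red; points are libraries, lines group means and whiskers SD. Both overexpressed da forms hold emc above every control library, and the knock-down holds it below.

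Monomeric da overexpression addressed what an excess of the E protein does to progenitors. The Notch target genes E(spl)m6-BFM and E(spl)m7-HLH and the genes mira and neur rose. E(spl)m6-BFM, of the E(spl) complex of Notch targets, rose from 4.21 ± 0.677 to 232 ± 36.2 CPM (log2 change 5.78 ± 0.47, adjusted p = 3.3e-05), and E(spl)m7-HLH from 15.2 ± 2.11 to 112 ± 4.03 CPM. Mira, whose product segregates fate determinants in neuroblasts, rose from 43.9 ± 5.58 to 143 ± 24.8 CPM (log2 change 1.70 ± 0.15, adjusted p = 5.16e-05). The ubiquitin ligase gene neur, which acts in Notch signalling, rose from 20.9 ± 3.25 to 81.7 ± 6.78 CPM (adjusted p = 0.000181). The septate junction gene Tsp2A rose as well (log2 change 2.11 ± 0.22, adjusted p = 0.000144). The peptide hormone genes CCHa1 and AstA of enteroendocrine cells fell, although the hormone list did not pass (5 of 11 lower, 1 higher, adjusted p = 0.175). CCHa1 went from 33.9 ± 13.4 to 1.70 ± 1.39 CPM (log2 change -4.35 ± 0.76, adjusted p = 0.00323), and AstA changed by -4.67 ± 0.85 (adjusted p = 0.00404). The progenitor gene esg (0.17, adjusted p = 0.496) and the Notch ligand gene Dl (-0.21, adjusted p = 0.804) did not pass.

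With da overexpressed, 1292 of 9540 genes rose and 893 fell, and 2185 changed in all. That total was 1379 without control replicate 2 and 1339 without da overexpression replicate 2. Gene lists given here with a single count had the same count adjusted over the list alone. Among the largest changes were CG12133 (2R, 9967231 to 9968388), at 36.4 ± 8.26 CPM and at least 1559-fold higher than controls with 0 counts, and Cyp309a2 (2L, 2564886 to 2573037), a cytochrome P450 gene at 78.5 ± 7.96 against 0.0558 CPM. Cyp309a2 also rose in the knock-down against the same controls. The gene CG6912 (3R, 15135138 to 15137004) fell from 39.9 ± 8.80 to 0.458 ± 0.0761 CPM. Of 14 Notch response genes, 7 rose and 0 fell, and 9 rose when adjusted over the list alone (median log2 change 0.91, list adjusted p = 0.00248, adjusted p = 0.78 with an estimated correlation). Progenitor genes gave 7 of 14 higher and 8 adjusted over the list alone (list adjusted p = 0.0266, and adjusted p = 0.78 with an estimated correlation), a call lost without da overexpression replicate 1 (0.221). Oxidative phosphorylation genes were lower as a list, with 7 of 58 falling and 3 adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.877 with an estimated correlation), which was lost without control replicate 1 (0.0855) or da overexpression replicate 2 (0.658). Proneural commitment genes split, with 6 higher and 4 lower, and 7 and 5 adjusted over the list alone (median log2 change 0.55, mean -0.07, list adjusted p = 0.308).

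The knock-down addressed what progenitors express when Da is lowered. The genes mira, Egfr, E(spl)mgamma-HLH, phyl, pros and Cdk1 fell. Mira went from 43.9 ± 5.58 to 8.98 ± 0.463 CPM (n = 3 each, log2 change -2.29 ± 0.14, adjusted p = 1.53e-05), and Egfr, the receptor of a growth signal for stem cells, fell from 65.7 ± 9.11 to 17.4 ± 3.85 CPM (adjusted p = 0.000351). E(spl)mgamma-HLH fell from 6.76 ± 0.966 to 0.520 ± 0.0498 CPM (adjusted p = 2.01e-05), and E(spl)m8-HLH, with 2 counts in the knock-down, was 199.9-fold lower (95% counting interval 55.1 to 1656). The gene phyl, which acts downstream of proneural proteins, fell (log2 change -5.98 ± 0.53, adjusted p = 0.00012), as did the enteroendocrine regulator pros, from 10.02 ± 4.43 to 1.51 ± 0.360 CPM (adjusted p = 0.00116). Both also fell with da overexpressed against the same controls, phyl by a log2 change of -2.88 ± 0.46 (adjusted p = 0.0021) and pros by -1.90 ± 0.41 (adjusted p = 0.00927, and 0.0648 without da overexpression replicate 1). The mitotic kinase gene Cdk1 fell from 19.9 ± 7.84 to 6.14 ± 0.232 CPM (adjusted p = 0.00446). The enterocyte genes mesh and nub were among 5 of 16 in their list that rose when adjusted over all genes tested. The list passed at the preset correlation (adjusted p = 0.0299) and not with an estimated correlation (adjusted p = 0.312). Mesh, of the smooth septate junction, rose from 26.8 ± 1.86 to 111 ± 26.1 CPM (adjusted p = 0.00288), and nub, an enterocyte factor, from 1.99 ± 0.858 to 6.41 ± 1.31 CPM (adjusted p = 0.00839). The V-ATPase gene Vha16-1 rose from 802 ± 77.5 to 1546 ± 169 CPM (adjusted p = 0.00113).

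Other marker genes gave less stable results in the knock-down. Esg was lower (log2 change -0.53 ± 0.15, adjusted p = 0.0342), a call lost without control replicate 2 (0.0581), control replicate 3 (0.0833) or knock-down replicate 1 (0.0940), 2 (0.101) or 3 (0.0571). Klu was lower (-0.62 ± 0.17, adjusted p = 0.0318), a call lost without control replicate 1 (0.0695), 2 (0.0685) or 3 (0.0817) or knock-down replicate 1 (0.0987) or 2 (0.103). Dl did not pass (-1.33 ± 0.46, adjusted p = 0.0702), but passed without a filter (0.00256), in the fit of the compared groups (0.0296), in that of all libraries (0.0137), with the block of knock-down and control libraries (0.0447) and without control replicate 3 (0.0267), da overexpression replicate 1 (0.0280) or da overexpression replicate 2 (0.0296). The proneural gene ase was lower (-3.28 ± 0.80, adjusted p = 0.019), a call lost without knock-down replicate 1 (0.0551) or 2 (0.0658). It was lower with da overexpressed too (-4.99 ± 1.12, adjusted p = 0.0111, and 0.0919 without da overexpression replicate 2). Tap did not pass in the knock-down (1.79 ± 0.75, adjusted p = 0.127), but passed in the fit of the compared groups (0.0241), with the block of knock-down and control libraries (0.0353) and without da overexpression replicate 1 (0.0282) or 2 (0.0325).

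In the knock-down 1073 of 9540 genes rose and 874 fell, 1947 in all. The total was 1095 without control replicate 1 and 937 without control replicate 2. With replicate numbers as a block it was 2031, and 2676 where the block covered knock-down and control libraries only, an alternative chosen after the data were seen. Among called genes with a mean of at least 10 CPM and no overlap between groups, CG9815 (2R, 23421521 to 23433354) had the steepest fall, from 39.2 ± 4.74 to 0.287 ± 0.121 CPM. Of 28 mitosis genes, 23 fell and 1 rose, with 24 lower when adjusted over the list alone (median log2 change -1.23, adjusted p = 3.42e-09, and adjusted p = 0.329 with an estimated correlation). DNA replication genes had 7 of 14 lower and 11 adjusted over the list alone (median -0.72, adjusted p = 0.00046, and adjusted p = 0.444 with an estimated correlation). In the Notch response list 7 of 14 genes fell, and 7 fell and 2 rose when adjusted over the list alone (adjusted p = 0.00102, and adjusted p = 0.312 with an estimated correlation). Proneural commitment genes had 6 lower and 1 higher, and 8 and 1 adjusted over the list alone (adjusted p = 5.8e-05, and adjusted p = 0.312 with an estimated correlation). Progenitor genes had 5 lower and 1 higher, and 6 and 2 adjusted over the list alone (adjusted p = 0.00103, and adjusted p = 0.312 with an estimated correlation). Gut peptide hormones fell in 7 of 11 cases, and adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.00472, and adjusted p = 0.312 with an estimated correlation).

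Of 86 ribosomal protein genes, 49 rose in the knock-down, and 77 when adjusted over the list alone (median log2 change 0.54, adjusted p = 5.66e-13, and adjusted p = 0.444 with an estimated correlation). RpS10b went from 729.6 ± 41.1 to 1149 ± 21.4 CPM (adjusted p = 0.00332). The list summed to 432054 ± 29596 CPM in the knock-down against 303022 ± 38287 in controls, a large part of all counts. TMM factors were 0.837 to 0.884 in the knock-down and 1.06 to 1.17 in controls, and these changes are relative to that scaling. Oxidative phosphorylation genes had 26 of 58 higher and 40 adjusted over the list alone (median 0.45, adjusted p = 4.62e-07, and adjusted p = 0.475 with an estimated correlation). V-ATPase genes had 13 of 24 higher and 1 lower, and 16 and 2 adjusted over the list alone (adjusted p = 8.05e-05, and adjusted p = 0.312 with an estimated correlation). Enterocyte regulators and structure genes had 5 of 16 higher and 6 adjusted over the list alone (adjusted p = 0.0299, and adjusted p = 0.312 with an estimated correlation), a call lost without control replicate 1 (0.0583), control replicate 2 (0.0519) or knock-down replicate 3 (0.0509), with the stricter filter (0.0599) and with the crossed block (0.0634). Enteroendocrine regulators and secretion genes had 7 lower and 1 higher, and 9 and 2 adjusted over the list alone (adjusted p = 0.0257, and adjusted p = 0.37 with an estimated correlation), which was lost without control replicate 1 (0.0637) and with the stricter filter (0.223). Digestive enzyme genes had 5 higher and 3 lower, and 8 and 4 adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.468 with an estimated correlation), lost without control replicate 3 (0.056) and with the stricter filter (0.0599). Antimicrobial peptide genes passed as higher with 2 of 6, and 4 adjusted over the list alone (adjusted p = 0.00472, and adjusted p = 0.312 with an estimated correlation), among them AttD (log2 change 3.82 ± 0.44). That list call was lost without a filter (0.0563) and in the fit of all libraries (0.271). The mitochondrial genome list passed as higher with 3 of 23 genes, and 0 adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.587 with an estimated correlation), lost without control replicate 2 (0.0704), control replicate 3 (0.0544) or knock-down replicate 2 (0.135), with the stricter filter (0.0599) and with the block of knock-down and control libraries (0.0707). Heat shock genes passed as lower with 3 of 13 (adjusted p = 0.0454, and adjusted p = 0.619 with an estimated correlation), which was lost without control replicate 1 (0.168), control replicate 2 (0.0643), da overexpression replicate 1 (0.0514), knock-down replicate 2 (0.183) or knock-down replicate 3 (0.0509), in the fit of all libraries (0.103) and with the crossed block (0.0588).

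The tethered homodimer addressed which changes Da makes without a heterodimer partner. The genes spdo, mira, Egfr and neur rose with da:da. Spdo, whose product acts in Notch trafficking, rose from 3.67 ± 0.974 to 71.9 ± 18.6 CPM (n = 3 each, log2 change 4.29 ± 0.31, adjusted p = 2.42e-06). Mira rose from 78.9 ± 18.2 to 566 ± 38.6 CPM (2.84 ± 0.22, adjusted p = 3.87e-06) and Egfr from 127 ± 25.4 to 549 ± 12.3 CPM (2.11 ± 0.21, adjusted p = 3.1e-05). The changes of spdo, mira and Egfr with da:da exceeded those with monomeric da by log2 differences of 3.07 (adjusted p = 0.000161), 1.21 (adjusted p = 0.0116) and 1.11 (adjusted p = 0.0391). Neur rose from 21.4 ± 3.81 to 216 ± 15.5 CPM (adjusted p = 1.73e-07), and E(spl)m8-HLH from 2.69 ± 0.747 to 14.8 ± 1.46 CPM (adjusted p = 1.74e-06). The hormone genes Dh31 (log2 change -2.92 ± 0.30, adjusted p = 4.81e-05) and CCHa1 (-2.47 ± 0.44, adjusted p = 0.00282) fell, whereas pros did not pass (0.36, adjusted p = 0.156). The hormone list summed to 6213 ± 1797 CPM with da:da against 4317 ± 225 in controls. In controls that sum was mostly NPF (3776 CPM), so it does not show how the other hormone genes moved. Dl (0.50, adjusted p = 0.0592, and 0.0305 without control replicate 2 or 0.0338 without da:da replicate 2, 0.0341 with the stricter filter and 0.0408 with DESeq2) and klu, an enteroblast gene (0.13, adjusted p = 0.641), did not pass either. Esg was higher with da:da (0.51 ± 0.14, adjusted p = 0.038), a call lost without control replicate 1 (0.113), 2 (0.0800) or 3 (0.111), da:da replicate 1 (0.0658), 2 (0.104) or 3 (0.0721) or scute replicate 2 (0.0578).

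With da:da 765 of 14190 genes rose and 925 fell, 1690 in all. CG3650 (2R, 24848994 to 24850200) rose from 0.102 ± 0.101 to 66.7 ± 7.33 CPM, and nvy, a co-repressor gene (2R, 24275734 to 24291084), from 0.804 ± 0.227 to 61.5 ± 8.27 CPM. The glutathione transferase gene GstD2 fell from 457 ± 127 to 37.2 ± 13.8 CPM. Progenitor genes had 6 of 14 higher and 1 lower, and 8 and 1 adjusted over the list alone (median log2 change 0.44, adjusted p = 1.23e-07, and adjusted p = 0.535 with an estimated correlation). Notch response genes had 5 of 15 higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.000286, and adjusted p = 0.749 with an estimated correlation). The proneural commitment list passed as higher with 3 genes each way, and 5 each way adjusted over the list alone (median 0.11, adjusted p = 0.0122, and adjusted p = 0.454 with an estimated correlation). DNA replication genes had 4 of 14 lower, and 10 adjusted over the list alone (adjusted p = 0.00331, and adjusted p = 0.932 with an estimated correlation). Mitosis genes did not pass as a list (adjusted p = 0.517). Scra was higher (log2 change 1.06 ± 0.13), but the mitosis list summed to 470 ± 17.8 CPM with da:da against 471 ± 50.9 in controls. Oxidative phosphorylation genes had 29 of 71 lower, and 49 lower and 2 higher adjusted over the list alone (median -0.37, adjusted p = 5.25e-08, and adjusted p = 0.888 with an estimated correlation). Of 17 genes of the mitochondrial genome, 8 fell, and 15 fell when adjusted over the list alone (adjusted p = 9.62e-06, and adjusted p = 0.749 with an estimated correlation). The list of enteroendocrine regulators and secretion passed as higher with 2 of 22 genes (adjusted p = 0.0224, and adjusted p = 0.932 with an estimated correlation), which was lost without control replicate 1 (0.0657), control replicate 3 (0.0662) or da:da replicate 3 (0.231), with the stricter filter (0.0755) and in the fit of all libraries (0.0749). Ribosomal protein genes passed as a list with 1 of 89 genes lower (adjusted p = 0.0224, and adjusted p = 0.932 with an estimated correlation), lost without control replicate 3 (0.296) or da:da replicate 3 (0.921) and with the stricter filter (0.169).

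Scute overexpression addressed what a proneural partner of Da does in the same cells. The enteroendocrine regulator pros, proneural genes and the cell cycle genes polo and CycE rose. Pros rose from 39.9 ± 4.24 to 547 ± 99.7 CPM (n = 3 each, log2 change 3.78 ± 0.16, adjusted p = 1.14e-08), and the proneural gene ase from 1.19 ± 0.102 to 80.4 ± 18.7 CPM (6.08 ± 0.20, adjusted p = 1.48e-09). Phyl rose from 2.87 ± 0.539 to 146 ± 7.85 CPM (adjusted p = 7.98e-10) and Dl from 32.7 ± 6.24 to 164 ± 11.1 CPM (adjusted p = 3.24e-07). E(spl)m8-HLH (3R, 26040240 to 26041008) rose from 2.69 ± 0.747 to 339 ± 15.1 CPM (log2 change 6.97 ± 0.20, adjusted p = 6.57e-10). The hormone genes CCHa1, from 11.7 ± 8.24 to 897 ± 155 CPM (adjusted p = 7.84e-07), and AstC (log2 change 4.11 ± 0.33) rose, whereas Mip (3L, 17344947 to 17349666) fell from 31.9 ± 3.87 to 0.663 ± 0.0977 CPM (adjusted p = 6.57e-10). The cell cycle genes polo, from 39.3 ± 1.38 to 148 ± 12.6 CPM (adjusted p = 2.98e-08), and CycE, from 4.27 ± 0.652 to 59.9 ± 20.8 CPM (adjusted p = 2.37e-07), rose. The neuropeptide receptor gene NPFR (3R, 6187315 to 6195403) rose from 2.51 ± 0.654 to 357 ± 25.2 CPM. Klu fell (log2 change -0.95 ± 0.13, adjusted p = 9.65e-05). Esg was lower (-0.44 ± 0.14, adjusted p = 0.025), a call lost with the stricter filter (0.0588) and without control replicate 2 (0.0826), control replicate 3 (0.0541) or scute replicate 3 (0.0541). Tap was higher (1.41 ± 0.46, adjusted p = 0.0245), a call lost with DESeq2 (0.0532) and without control replicate 1 (0.0887), control replicate 3 (0.0634) or scute replicate 3 (0.168).

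**Figure D2:**
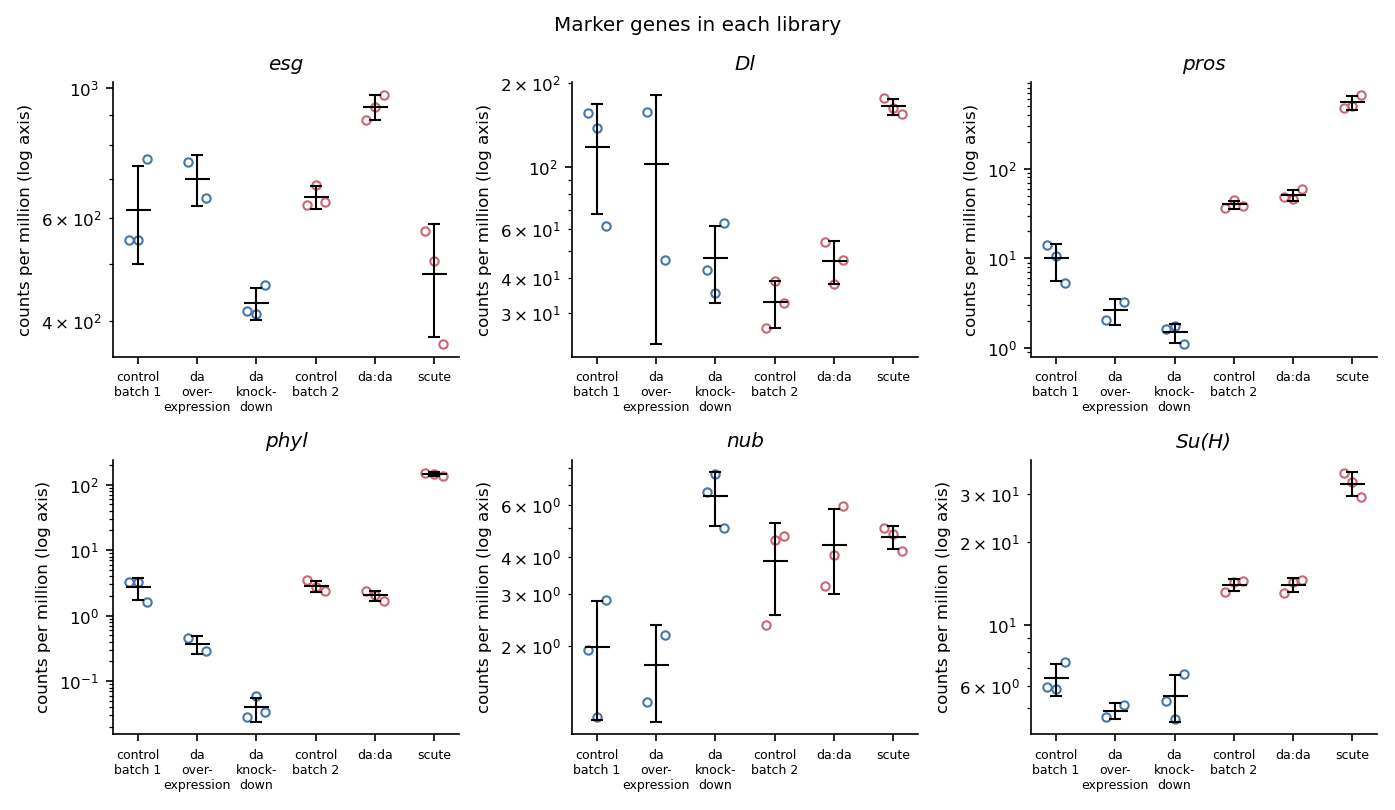
CPM of esg, Dl, pros, phyl, nub and Su(H) in each library on a log axis, by group, with batch 1 in blue and batch 2 in red; points are libraries, lines group means and whiskers SD. Pros, phyl and Dl are highest within batch 2 in the scute libraries, where pros averages 547 CPM.

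With scute 3235 of 14190 genes rose and 3154 fell, 6389 in all. Mitosis genes had 27 of 28 higher, also adjusted over the list alone (median log2 change 1.33, adjusted p = 4.93e-13, and adjusted p = 0.2 with an estimated correlation), and DNA replication genes 13 of 14 higher and 1 lower, counts that held adjusted over the list alone (1.61, adjusted p = 2e-06, and adjusted p = 0.29 with an estimated correlation). Of 22 enteroendocrine regulators and secretion genes, 21 rose (median 1.70, adjusted p = 1.56e-14, and adjusted p = 0.203 with an estimated correlation). Proneural commitment genes had 13 of 17 higher and 0 lower (median 1.19), and this call held at both settings (adjusted p = 5.97e-10, and 0.0108 with an estimated correlation). The bHLH partner list also held at both, with 11 of 23 higher and 1 lower, and 11 and 2 adjusted over the list alone (adjusted p = 7.79e-05, and 0.029 with an estimated correlation). Gut peptide hormones had 9 of 12 higher and 2 lower, and the list did not pass (adjusted p = 0.18). Notch response genes had 10 of 15 higher and 4 lower (adjusted p = 5.92e-06, and adjusted p = 0.2 with an estimated correlation), and progenitor genes 4 higher and 6 lower, not passing (adjusted p = 0.942). Enterocyte genes had 10 of 16 higher and 1 lower (adjusted p = 0.0015, and adjusted p = 0.29 with an estimated correlation).

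Of 89 ribosomal protein genes, 82 fell with scute and 4 rose (median log2 change -0.99, adjusted p = 4.07e-17, and adjusted p = 0.516 with an estimated correlation). RpLP0 went from 5708 ± 276 to 2488 ± 324 CPM (adjusted p = 1.12e-05). The list summed to 152276 ± 23463 CPM with scute against 295152 ± 17872 in controls, a large part of all counts. TMM factors were 1.17 to 1.22 with scute and 0.862 to 0.907 in controls, and these changes are relative to that scaling. Oxidative phosphorylation genes had 43 of 71 lower and 4 higher, and 43 and 5 adjusted over the list alone (adjusted p = 0.000157, and adjusted p = 0.616 with an estimated correlation), and genes of the mitochondrial genome 16 of 17 lower and 1 higher (adjusted p = 0.000159, and adjusted p = 0.516 with an estimated correlation). The V-ATPase list did not pass (adjusted p = 0.127), with 10 of 28 lower, such as Vha68-2 (log2 change -1.88), and 4 higher, such as Vha68-1 (3.65). Heat shock genes had 9 of 14 higher and 13 adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.77 with an estimated correlation), a list call lost without control replicate 1 (0.0515), control replicate 3 (0.0603) or scute replicate 3 (0.0511), with the stricter filter (0.215) and with batch 2 counts halved (0.0621). EGFR and JAK-STAT targets did not pass as a list (adjusted p = 0.0776), with 6 lower, among them vn, an EGFR ligand gene (log2 change -3.25 ± 0.26), and 3 higher.

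Scute was also compared directly with da:da within batch 2. Fer1, a bHLH gene, was higher with scute at 139 ± 33.96 CPM against 0.327 ± 0.272 (n = 3 each, log2 change 8.79 ± 0.54, adjusted p = 1.35e-07), and CCHa1 differed by 8.73 ± 0.54 (adjusted p = 1.65e-07). Lower with scute were CG3650 (-8.64 ± 0.36), emc (-4.30 ± 0.18, adjusted p = 1.06e-08), Egfr (-2.23 ± 0.21) and the cytokine gene upd2 (-4.46 ± 0.27, adjusted p = 1.25e-07). In all, 3042 genes were higher and 3012 lower with scute. Mitosis genes had 27 of 28 higher and 28 adjusted over the list alone (adjusted p = 5.61e-15, and adjusted p = 0.184 with an estimated correlation). Enteroendocrine regulators and secretion genes had 17 higher and 1 lower, and 19 and 1 adjusted over the list alone (adjusted p = 3.45e-11, and adjusted p = 0.319 with an estimated correlation). The progenitor list was lower with scute, with 8 genes lower and 1 higher (adjusted p = 0.00784, and adjusted p = 0.55 with an estimated correlation), a call lost with the stricter filter (0.0625).

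Da overexpression and da knock-down were compared directly within batch 1. Higher with overexpression were emc (log2 difference 5.95 ± 0.18, adjusted p = 1.05e-07), mira (3.99 ± 0.16, adjusted p = 6.61e-07) and Egfr (2.99 ± 0.23, adjusted p = 1.31e-05). E(spl)m8-HLH was 981-fold higher (95% counting interval 271 to 8106). The hormone genes CCHa1 (1.75, adjusted p = 0.135) and AstA (-0.27, adjusted p = 0.84), which fell in both against controls, did not pass. In all, 1522 genes were higher and 1346 lower with overexpression. Notch response genes had 8 higher and 0 lower (adjusted p = 7.13e-07, and adjusted p = 0.232 with an estimated correlation), and oxidative phosphorylation genes 39 of 58 lower, 46 adjusted over the list alone (adjusted p = 5.38e-09, and adjusted p = 0.682 with an estimated correlation).

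Changes of different batches were compared as differences of log2 changes, each against its own controls. Between da:da and monomeric da, 352 genes had a more positive and 633 a more negative change with da:da. Syt4, a synaptotagmin gene, differed by 7.67 ± 0.51 (adjusted p = 3.93e-08) and CG6912 by 5.94 ± 0.32, and Cyp309a2 by -10.84 ± 0.49 (adjusted p = 3.22e-10). The list of enteroendocrine regulators and secretion was more positive with da:da, with 3 genes higher (adjusted p = 0.0104, and adjusted p = 0.61 with an estimated correlation), which was lost without da overexpression replicate 1 (0.0734) or da:da replicate 3 (0.0806). Between scute and monomeric da, 1770 genes had a more positive and 2246 a more negative change with scute. Phyl differed by 8.62 ± 0.41 (adjusted p = 1.33e-10). Mitosis genes were more positive with scute in 22 of 28 cases and 25 adjusted over the list alone (adjusted p = 8.5e-13, and adjusted p = 0.2 with an estimated correlation). Proneural commitment genes held at both settings, with 4 more positive and 1 more negative (adjusted p = 0.000253, and 0.047 with an estimated correlation).

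Agreement between comparisons was measured across 9492 genes tested in both batches, which are not independent replicates. The log2 changes with da:da and da had a correlation across genes of 0.47 (Spearman 0.44). Of 826 genes called in both, 95.0% changed in the same direction, with 450 higher in both against 93.5 by chance and 335 lower in both against 83.0. Knock-down and da:da shared 545 called genes, of which 24.0% had the same direction. Da and scute shared 1469 with 72.0%, and knock-down and scute 1328 with 33.3%. Comparisons with the same controls were set against simulated unchanged groups. Da and its knock-down had a correlation across 9538 genes of 0.21 and shared 718 called genes, 61.7% of them in the same direction. Simulated groups gave a mean correlation of 0.43 but a covariance of 0.0619 against 0.276, and at most 1 gene called in both in the same direction. With no gene changed in the simulation, its adjusted threshold was stricter than the real one, so the call counts are not alike. Between da:da and scute the correlation across genes was 0.31, below the simulated mean of 0.508 (0.487 to 0.533), while the covariance was 0.233 against 0.0574 simulated. Neither of the correlations with shared controls exceeded its simulated mean. The simulated changes hold noise only, so that does not show whether more than the controls is shared. Both covariances lay above the highest simulated ones, 0.0674 for da with its knock-down and 0.0614 for da:da with scute. Between da:da and scute 78.4% of 1279 shared called genes had the same direction.

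Genes of other cell types moved with several groups. Haemocyte markers fell with da in 3 of 5 cases (list adjusted p = 0.144), for example Col4a1 from 3.55 ± 2.30 to 0.0976 ± 0.0527 CPM (adjusted p = 0.00258). In the knock-down the same number fell, with 1 rising when adjusted over the list alone (list adjusted p = 0.0274, and adjusted p = 0.312 with an estimated correlation). That list call was lost without da overexpression replicate 1 (0.051), whose library shares the fit, or knock-down replicate 3 (0.0533), and with the stricter filter (0.158). The haemocyte sum was higher in the knock-down, at 239 CPM (230.6 to 251.8) against 196 CPM in batch 1 controls (172.7 to 220.2). The list call therefore does not show less haemocyte RNA in the knock-down. Neuron and glia markers rose with scute in 7 of 9 cases and 8 adjusted over the list alone (median log2 change 2.34), a call that held at both settings (adjusted p = 9.28e-09, and 0.029 with an estimated correlation), with nrv3 going from 56.3 ± 7.80 to 1055 ± 237 CPM. With da, visceral muscle markers had 3 of 10 higher (list adjusted p = 0.359), at levels such as 0.642 CPM for Mhc against 0.112, and fat body markers had 0 of 4 called (list adjusted p = 0.836). Trachea markers with da summed to 85.4 ± 8.03 CPM against 28.9 ± 5.46, with 1 of 4 higher and 1 lower, and 2 and 1 adjusted over the list alone (list adjusted p = 0.323), a sum that was mostly Cht2, at 77.1 ± 9.53 against 16.5 ± 6.39 CPM (adjusted p = 0.000241). Neuron and glia markers with da summed to 72.9 ± 0.933 against 44.4 ± 1.43 CPM, with 2 of 5 higher (list adjusted p = 0.359). In the knock-down, germline markers summed to 2.24 ± 0.367 against 6.06 ± 1.88 CPM, with 2 of 5 lower (list adjusted p = 0.0536). Fat body markers there summed to 421 ± 17.04 against 337 ± 16.2 CPM, with 1 of 4 higher (list adjusted p = 0.798). Trachea markers summed to 39.6 ± 0.221 against 28.9 ± 5.46 CPM, with 1 of 4 higher (0.651). Visceral muscle markers had 1 of 10 higher (0.732), neuron and glia markers 1 of 5 lower (0.744) and Malpighian tubule markers 0 of 2 called (0.382). With da:da, fat body markers summed to 524 ± 37.4 against 728 ± 55.5 CPM, with 2 of 7 lower (list adjusted p = 0.693), and haemocyte markers to 163 ± 1.11 against 201 ± 1.72 CPM, with 1 of 9 lower (list adjusted p = 0.9751). Neuron and glia markers had 1 of 9 lower with da:da (list adjusted p = 0.896), and visceral muscle, trachea, germline and Malpighian tubule markers had 0 called. Trachea markers with scute had 4 of 7 higher and 2 lower (median 0.66, list test downward, adjusted p = 0.711), with Cht2 falling from 19.7 ± 0.211 to 1.48 ± 0.520 CPM. Germline markers had 4 of 7 higher with scute (list adjusted p = 0.358), and Malpighian tubule markers 0 of 5 (adjusted p = 0.811). Among transgene markers with scute 1 of 3 rose (adjusted p = 0.817).

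**Figure D3:**
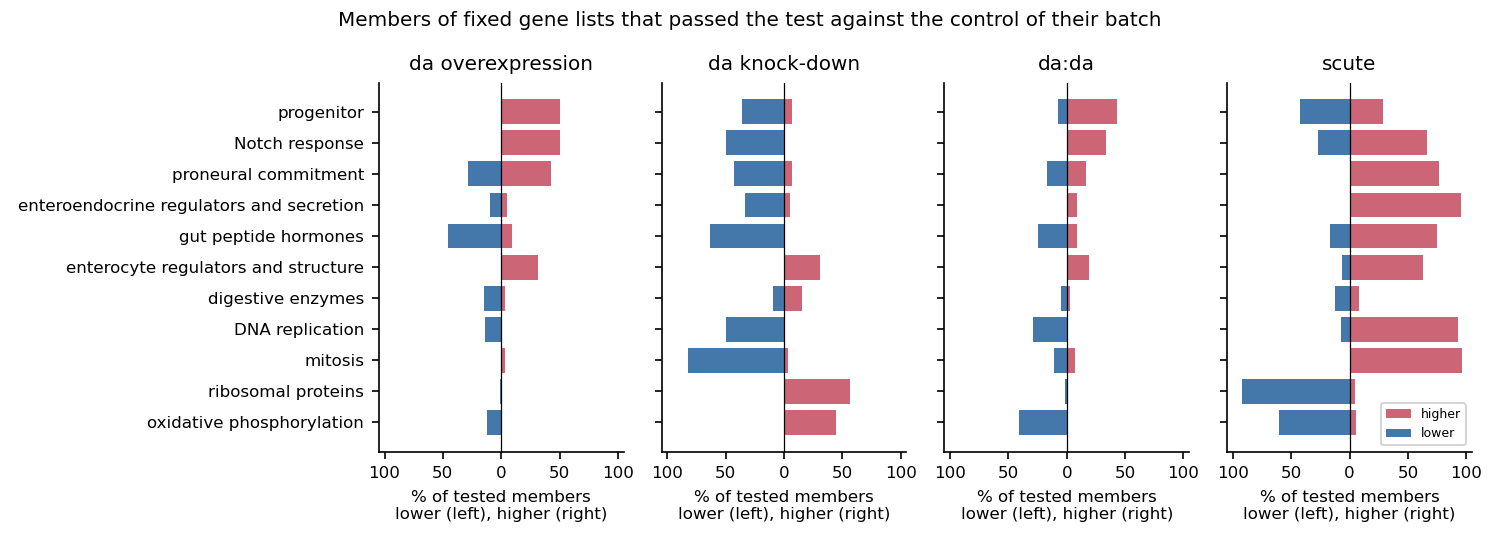
Percent of tested members of 11 gene lists that passed as lower (left) or higher (right) in each of the 4 comparisons with the group's own control. Mitosis genes lie to the left in the da knock-down (23 of 28) and to the right with scute (27 of 28).

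The authors' deposited comparisons list 9986 genes. They call 3255 genes changed with da, 2942 in the knock-down, 1772 with da:da and 5849 with scute. Of these, 2030, 1848, 1483 and 5618 were also called here, 100% of them in the same direction. The log2 changes had correlations across genes of at least 0.9989 with the authors' values in these 4 comparisons.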

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

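The tests of the enteroendocrine pattern, of the higher and lower parts of the shared da pattern, and of single heat shock genes were chosen after the result was seen. In the joint fit of all libraries, the test of the difference between changes singled out 985 genes whose change with da:da differed from that with monomeric da. The 5 with the lowest p on the positive side were CG6912 (5.94), GstE1 (3.25), CG9801 (3.21), Syt4 (7.67) and Npc2a (2.37), as differences of log2 changes. On the negative side were NT5E-2 (-5.69), Cyp309a2 (-10.84), CG10208 (-2.98), kermit (-2.46) and CG33099 (-4.20). NT5E-2 and Cyp309a2 also rose in the da knock-down against the same batch 1 controls, by 6.69 and 10.93. These differences are thus not particular to da overexpression and include the level of the batch 1 controls. For Cyp309a2 that level, 0.0454 to 0.0711 CPM, was low as in every batch 2 library (0.127 to 0.609 CPM). Only the da overexpression (72.8 to 84.1 CPM) and knock-down libraries (107 to 121 CPM) stood apart. The same test singled out 4016 genes between scute and monomeric da. There the positive side held sc (12.42), RhoGAP100F (4.88), Syt4 (11.19), lncRNA:noe (6.99) and phyl (8.62). Phyl fell in both da groups against the batch 1 controls, by -2.88 with da and -5.98 in the knock-down, so its difference includes their level as well. The negative side held NT5E-2 (-7.09), CG10208 (-5.09), CG10184 (-5.12), SWIP (-4.12) and Cyp309a2 (-11.44). Both differences set batches with unlike read lengths against each other, which the controls remove only as far as a batch acts alike on all its libraries.

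Reads outside annotated exons, which no comparison uses, took a larger share in both overexpression groups of batch 2 than in their controls. Their mean share was 5.72% with da:da and 6.95% with scute against 4.92% in controls (n = 3 each). With 3 libraries against 3 the smallest exact two-sided p is 0.1.

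In 125 genes, da overexpression and da knock-down gave called changes of at least 2 in log2 size with the same sign, 25 higher, such as Cyp309a2, and 100 lower, among them the enteroendocrine genes CCHa1, AstA and dimm, the proneural gene ase, phyl, which acts downstream of such genes, and the haemocyte genes Col4a1 and vkg, while 32 genes had opposite signs. The simulated unchanged groups reached 0 such genes at most. With no gene changed, at most 1 gene was called in both there, and genes were drawn independently of each other. The simulation therefore cannot decide on chance deviations of the shared controls, which stay open. A response to any departure of the da level from normal predicted that da:da moves these genes at least as often as genes changed by da overexpression alone. In the whole set da:da moved 16.9% the same way against 31.0% of the others (Fisher exact p = 0.00186). However, 99 of the 124 genes tested there were lower and 336 of the 390 others higher, so that test mixes directions. Within 1 direction the shares were 12% (3 of 25 genes) against 32.1% for the higher part (Fisher exact p = 0.0419). For the lower part they were 18.2% against 24.1% (Fisher exact p = 0.406). Counts of da rose less with da:da than with monomeric da, in another batch, and do not compare the doses of the constructs. The comparison genes were picked as changed by da overexpression. The test therefore cannot decide, and such a response stays open for both parts. The genetic background of the control cross predicted neighbours within the set, which were found. Of the genes, 29.6% had another of the set among the 3 tested genes on either side (upper limit of random sets 14.4%). The share was 16% in the higher part (limit 8%) and 29% in the lower part (limit 14%). Position cannot tell the background of the control cross from that of the da crosses, and Cyp309a2 was low in the controls of both batches. Neighbouring copies of a gene may also share regulation or reads. A larger share of other cells in the batch 1 controls, not tested, stays open too.

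Enteroendocrine genes (list adjusted p = 1.56e-14, and 0.203 with an estimated correlation) and neuronal genes (9.28e-09, and 0.029) were higher with scute. Mature enteroendocrine cells of all types carried into the gate are argued against by NPF, the most abundant hormone gene of the batch 2 controls. NPF fell from 3776 to 1811 CPM (log2 change -1.06, adjusted p = 0.000621), while Tk rose by 0.83 and AstC by 4.11. The batch 2 controls already held much hormone RNA, mostly NPF, with the hormone list at 4317 CPM against 298 in batch 1 controls. The 2 batches differ in read length. The hormone RNA already in the batch 2 controls limits this argument. In camera, 0 of the lists of visceral muscle (adjusted p = 0.811), haemocyte (0.809), trachea (0.711) and fat body markers (0.881) passed as higher. This argues against a loss of gate purity for those cell types only. The enterocyte list passed as higher at the preset correlation and not with an estimated one (adjusted p = 0.29). It had 10 genes higher and 1 lower and summed to 2307 ± 204 against 1084 ± 33.0 CPM. Enterocytes carried into the gate stay open. A response of the sorted cells to Scute is consistent with these values as a hypothesis, found and tested on the same data. More cells of an enteroendocrine type that is rich in AstC and poor in NPF stays open and could come from the same response.

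Of 14 heat shock genes, 9 were higher with scute, a list call (adjusted p = 0.0339) lost with an estimated correlation (0.77), the stricter filter (0.215), halved batch 2 counts (0.0621) and without control replicate 1 (0.0515) or control replicate 3 (0.0603). Hsp26 was uneven, at 325, 587 and 2364 CPM in replicates 1, 2 and 3. Stress in scute replicate 3 alone could not be decided for the list, whose adjusted p went from 0.0339 to 0.0511 without that library. As the sole cause for single genes it is argued against, since 7 genes of the list passed as higher without that library, a count that does not say which of the 9 they were.

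Other divisions of the same 6 libraries into 3 and 3 gave at most 0 called genes for the da knock-down, against 1947 in the real groups. For da:da the values were 0 against 1690, for scute 1 against 6389, and for scute against da:da 0 against 6054. In each comparison 1 of 10 divisions, the real one, gave that many, and 10 divisions are too few for a share under 0.05. The other divisions mix both real groups on each side, so a real difference widens their spread. Their low counts are therefore largely built in and do not measure the strength of the real difference. In the knock-down, where replicate numbers were read as pairs, the real division parts 3 pairs, and the 3 others that also part 3 pairs gave 0.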

How the results depend on the processing

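The halved batch 2 counts, the block with knock-down and control libraries only and the block with crossed numbers were chosen after the data were seen. Of the counts of called genes under all alternatives, 144 stayed within 1.5 times the value reported and 10 did not. Named genes kept direction and side of the threshold in 8654 cases, gained the call in 36, lost it in 453 and reversed in 12, all 12 among changes that had not passed. Lists kept their call in 1162 cases and lost it in 118. These losses were not spread evenly over the alternatives. The estimated inter-gene correlation alone removed most of the list calls, among them all those of the da, knock-down and da:da comparisons with controls. Most list calls therefore rest on the preset correlation, and the pooled counts do not show that they are robust to this choice.

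A required absolute log2 change of 1 left 1195 genes for da, 944 for the knock-down, 706 for da:da, 3220 for scute, 2946 for scute against da:da and 1565 for da against knock-down, fewer by construction. With 1 library left out, counts ranged from 1339 to 2118 for da, 937 to 2163 for the knock-down, 1196 to 1863 for da:da, 5627 to 6553 for scute, 5174 to 6107 for scute against da:da, 1940 to 2879 for da against knock-down, 680 to 1057 for the difference of da:da and da and 3429 to 4162 for that of scute and da. In the da comparison, the counts below 1.5 times came without control replicate 2 (1379) and da overexpression replicate 2 (1339), and in the knock-down without control replicate 1 (1095) and replicate 2 (937). A replicate block gave 2438 genes for da, 2031 for the knock-down, 1755 for da:da and 6361 for scute, and the crossed block 2706 for da and 2374 for the knock-down. DESeq2 gave 2376, 2211, 1942 and 6418, and kept 2100 of the 2185 da genes.

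The percent of shared calls in the same direction ranged, with 1 library left out, from 93.6 to 95.8 for da:da with da, 20.7 to 26.3 for knock-down with da:da, 69.8 to 74.3 for da with scute, 30.9 to 38.4 for knock-down with scute, 57.4 to 70.8 for da with knock-down and 73.5 to 79.7 for da:da with scute. For da:da with da the replicate block gave 92.8 and the crossed block 92.6. The stricter filter gave 37.3 for knock-down with scute, 56.7 for da with knock-down and 75.8 for da:da with scute. The cause was not tested.

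Reversals concerned genes whose change had not passed. With da and 1 library left out, the log2 change of w ranged from -0.418 to 0.0709, that of Dl from -1.35 to 0.415, that of nub from -0.616 to 0.175 and that of tap from -0.653 to 2.79, and tap passed without da overexpression replicate 1. With da:da, Su(H) ranged from -0.0430 to 0.0476 and nub from -0.0769 to 0.369. Su(H) was also -0.00179 without a filter. The cause was not tested. Where a library left out leaves 1 da overexpression library, that library is assumed to vary like the other groups. In simulated data the differences of changes recovered 19.4% of 2-fold changes for da:da and 25.4% for scute. Far fewer genes were changed in the simulation than were called in the real differences, so these shares need not hold there. Genes not called may still differ by that much.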

Other observations

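The EGFR ligand gene vn fell with da (log2 change -1.04 ± 0.18, adjusted p = 0.00276), da:da (-1.85 ± 0.24, adjusted p = 0.000314) and scute (-3.25 ± 0.26, adjusted p = 9.15e-07). The protease gene rho, which acts in the release of EGFR ligands, rose with da (1.69 ± 0.19), da:da (0.86 ± 0.11) and scute (1.31 ± 0.11). The cytokine gene upd2 rose with da:da, from 19.3 ± 6.53 to 53.4 ± 11.4 CPM (n = 3 each, adjusted p = 0.0014), and fell with scute (log2 change -2.99 ± 0.25, adjusted p = 1.68e-06, a value chosen after it was seen). The cytokine gene upd3 fell with scute, from 45.9 ± 10.5 to 10.1 ± 2.05 CPM (adjusted p = 1.57e-06). The V-ATPase subunit gene Vha100-1 rose with da, from 34.9 ± 3.62 to 140 ± 3.84 CPM (n = 2 with da and 3 controls, adjusted p = 4.14e-05), and with da:da (log2 change 0.83 ± 0.12, adjusted p = 0.0005).

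With scute, the maltase genes Mal-A3 and Mal-A2 rose, by 4.18 ± 0.36 (adjusted p = 2.03e-06) and 3.35 ± 0.36 (adjusted p = 9.97e-06), and Mal-A6 fell (-1.68 ± 0.34, adjusted p = 0.00158). With da, Mal-A6 fell (log2 change -2.30 ± 0.29, adjusted p = 0.000483), as did Mal-A5 (-3.17 ± 0.33) and, chosen after its value was seen, Mal-A3 (-2.90 ± 0.76, adjusted p = 0.0223). Mal-A3 also fell in the knock-down against the same controls (-2.34, adjusted p = 0.0284). The antimicrobial peptide gene AttD fell with da:da (-4.85 ± 0.94, adjusted p = 0.00491) and rose in the da knock-down (3.82 ± 0.44, adjusted p = 0.000484). The collagen genes Col4a1 and vkg fell in the knock-down by -4.28 ± 0.68 and -4.64 ± 0.70, at levels of 3.55 and 3.54 CPM in controls, and with da by -5.09 ± 0.85 and -3.83 ± 0.76 against the same controls.

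The eye colour gene v, often a marker of transgenic insertions, had 98 counts over the knock-down libraries and 0 in the controls of batch 1, at least 41.3-fold higher. It also had 0 counts with da overexpressed. The counts of v do not show from which construct they come.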
